A study of Rattus norvegicus with 3 samples.

How the data were processed

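Single-cell 3' RNA libraries of wound skin from diabetic rats were analysed, 1 library for each of 3 groups: untreated, hydrogel and CO hydrogel. Per the labels, the animals were male Sprague-Dawley rats given 65 mg/kg streptozotocin, with blood glucose over 16.7 mM, and wounds of 15 mm were taken after 7 days. The number of animals per library is not given in the labels. Tissue was dissociated with an enzyme kit at 37 °C and red cells were lysed, per the labels.

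The deposited matrices hold counts, raw UMI counts per gene and barcode, which the authors made with Cell Ranger. Per the file headers the version was 6.0.1, while the submitters' processing notes name Cell Ranger 7.0.0, Seurat 4.2.0 and DESeq 1.38.0 and genome build rn6. Each deposited barcode has at least 500 UMIs. The matrices list 32883 features, of which 21273 have a symbol that could be named. Gene symbols were taken from the deposited feature names, and listed genes without such a name, among them Col1a2, Pecam1 and Gapdh, were not analysed here.

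Before the data were examined, the cell filter, doublet rate, clustering, marker lists, gene lists, comparisons, rule for named genes and alternatives were fixed. Cells were kept with at least 500 UMIs, 300 genes and at most 20% mitochondrial UMIs. The barcodes with the highest Scrublet scores were removed as doublets at 0.8% per 1000 barcodes, which was 9.31%, 10.8% and 11.4% of the untreated, hydrogel and CO hydrogel barcodes. Scrublet's own threshold called 0, 625 and 652. Of 43701 barcodes 35278 were kept. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 20 neighbours gave 30 Leiden clusters at resolution 1 over the 3 libraries together. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors alone.

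Clusters were named by markers of 18 cell classes. A cluster took the class with the highest marker score if the score was at least 0.2, each of at least 3 markers was detected in 20% of its cells, and its 10 leading genes did not hold more markers of another class. The score is the mean over markers of the level in the cluster relative to its highest level in any cluster. A cluster whose cells had far fewer UMIs than the median of their library and no marker of the class among its leading genes was also left unnamed, which applied to cluster 13. In all, 7 clusters stayed unnamed. The markers were fixed, but this scoring, its conditions and its thresholds were chosen after several scorings had been tried on the data. Classes with at least 100 cells in each library entered ratios between libraries, which left out keratinocyte-like cells (93 untreated) and T or NK-like cells (99 untreated), so the keratinocyte gene lists were not compared.

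Counts were summed per class and library and scaled to counts per 1000000 UMIs of the class (CPM). Ratios were taken for 3 pairs of libraries, with exact conditional binomial intervals, for genes with at least 100 UMIs over both libraries. With 1 library per group no test was made, and all 95% intervals cover counting error only. A share of 0 was given the limit that 3 counts allow. Of 20 gene lists fixed in advance, those for each class were read as the median log2 ratio of members with at least 20 UMIs, beside the number of 10000 random lists of matched expression with a lower median, as a description of these libraries. Medians of whole lists with under 6 measured members are not reported, a rule set after the data were seen, while medians over the 3 to 5 members left after dropping genes higher elsewhere are given without an interval.

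Named genes were the 10 highest and 10 lowest ratios per class and pair among genes with at least 100 UMIs, a UMI in at least 5% of the cells of the class in 1 of the libraries and a symbol, leaving out mitochondrial, ribosomal, hemoglobin and immunoglobulin genes and genes over 5 times higher in another class, which free RNA can bring. For genes going with Cxcl14, the 10 in each direction with the same sign in all 3 libraries and the largest smallest ratio were named, with at least 20 UMIs in each library. After the values were seen, mast and adipocyte classes were added to the comparison with other classes, the pattern of left-out names was tightened, and a limit of 3 counts replaced an added 0.5 for genes at 0.

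For Cxcl14 shares every cell was thinned to 1000 UMIs by 1 random draw, and 33496 cells reached that depth. Over 100 draws the share of fibroblast-like cells with a Cxcl14 UMI ranged from 10.3% to 12.5% untreated, 11.8% to 14.2% hydrogel and 9.06% to 10.3% CO hydrogel. Alternatives were a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial), no doublet removal, resolution 2, clustering each library by itself, TMM factors, the mean of per-cell CPM, thinning to 2000 UMIs or none, no minimum count with 0.5 counts added, and, chosen after seeing the data, list medians without genes over 5 times higher in another class, shares without neutrophil-like cells in the total, cluster 13 counted as neutrophil-like, and Cxcl14-negative cells weighted to the clusters of the positive ones. The steps were tested on simulated data with changes planted in the pair CO hydrogel and hydrogel: 98.9% of 93 fibroblast-like and 100.0% of 100 macrophage or monocyte-like genes changed 3-fold were called at 2-fold, against 0% and 0.0109% of unchanged genes. The simulated counts held counting error only, with no variation between cells, animals or specimens. These rates therefore check the computation and do not give the rate of false calls in the real libraries.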

Results

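Single-cell RNA sequencing was done on full-thickness skin wounds of male Sprague-Dawley rats made diabetic with streptozotocin, a toxin of pancreatic beta cells. Wounds of 15 mm were left untreated, covered with a hyaluronic acid hydrogel, or covered with a hyaluronic acid hydrogel that releases carbon monoxide (CO), and were taken after 7 days. There was 1 library per group, so no difference between groups was tested, no p-value is given, and no difference has a replicate check. The deposited matrices held 12883 barcodes and 78233883 UMIs for the untreated wound, 15442 barcodes and 109148721 UMIs for the hydrogel wound, and 15376 barcodes and 109718517 UMIs for the CO hydrogel wound. After filtering, 10550, 12069 and 12659 cells were kept, with medians of 2634, 5941 and 6076 UMIs per cell in the same order. All intervals are 95% intervals that cover counting error only, exact binomial for shares and exact Poisson or conditional binomial for UMI counts. Eif2s3y, a Y-linked gene read to check the label of male animals, was detected in fibroblast-like cells of all 3 libraries at 46.7, 50.1 and 52.2 CPM (UMIs of the gene per 1000000 UMIs of the class). Kdm5d, also Y-linked, was at 10.9, 11.6 and 15.1.

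The first comparison asked which cells each wound held. The most numerous class was neutrophil-like in the untreated wound, macrophage or monocyte-like in the hydrogel wound and fibroblast-like in the CO hydrogel wound. Fibroblast-like cells made up 12.2% of kept cells in the untreated library (interval 11.6 to 12.8), 14.4% in the hydrogel library (13.8 to 15.0) and 39.2% in the CO hydrogel library (38.3 to 40.0). The CO hydrogel share was 2.73 times the hydrogel share and 3.21 times the untreated share. Neutrophil-like cells made up 53.0% (52.0 to 54.0), 15.7% (15.0 to 16.4) and 3.52% (3.20 to 3.85), which was 4.46-fold lower with the CO hydrogel than with the hydrogel and 15.1-fold lower than without treatment. Macrophage or monocyte-like cells made up 19.3% (18.6 to 20.1), 37.6% (36.8 to 38.5) and 21.7% (21.0 to 22.4). Among cells that are not neutrophil-like, a total chosen after seeing the data, fibroblast-like cells were 25.9%, 17.1% and 40.6%, so their share was then lower with the hydrogel than without treatment. Macrophage or monocyte-like cells were 41.1%, 44.6% and 22.5% of that total, so their share was then lower with the CO hydrogel than without treatment. The neutrophil-like class differed in makeup too: cluster 1, led by the cytokine genes Il23a, Cxcl3 and Ccl3, held 61.4% of it in the untreated, 11.0% in the hydrogel and 3.60% in the CO hydrogel library, and cluster 2, led by Slc16a3 and Csf3r, held 19.6%, 87.3% and 95.5%.

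Endothelial-like cells were 2.19% of untreated, 5.10% of hydrogel and 7.32% of CO hydrogel cells, and 4.66%, 6.05% and 7.59% of those that are not neutrophil-like. Mural-like cells, the class of pericytes and vascular smooth muscle, were 5.51%, 7.92% and 8.85%, an order that turned to 11.7%, 9.39% and 9.17% of cells that are not neutrophil-like. T or NK-like cells were 0.938%, 3.92% and 3.22%, and keratinocyte-like cells 0.882%, 0.953% and 1.86%, or 1.88%, 1.13% and 1.93% without neutrophil-like cells. Mast or basophil-like cells were 0.0569%, 0.273% and 0.695%, from 6, 33 and 88 cells. Proliferating-like cells were 2.04%, 1.24% and 1.86%. Adipocyte-like cells were 0 of 10550 untreated cells, which allows a share of up to 0.0284%, and 0.0497% and 0.0711% of the treated libraries, from 6 and 9 cells. The class held no cell of either treated library under the stricter cell filter, with no doublets removed or with each library clustered by itself. Cells in 7 clusters that met no naming rule were 3.89%, 12.8% and 11.8%. Of these, cluster 13 scored highest for neutrophil markers (0.584) but was left unnamed for few UMIs and no neutrophil marker among its 10 leading genes. Its median of 1821 UMIs lay between those of the neutrophil-like clusters 2 (1712) and 1 (1918), and it held 1.01%, 7.57% and 0.0869% of cells. Counted as neutrophil-like, an alternative chosen after seeing the data, it raises that share to 54.0%, 23.2% and 3.60%, and the hydrogel share is then 6.45 times that of the CO hydrogel library. Shares sum to the whole library, so a large neutrophil share lowers all others, and the median depth of neutrophil-like cells (1951, 1782 and 1309 UMIs) was far below that of fibroblast-like cells (16446, 13494 and 9183).

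The classes were named from markers fixed in advance, and their leading genes by fold were as follows. Fibroblast-like cells were led by Sfrp4, Fndc1, Has1, Dcn and Cxcl13. Macrophage or monocyte-like cells were led by Spp1, Cybb, C1qa, C1qc and C1qb, the last 3 encoding complement C1q. Neutrophil-like cells were led by Il1r2, G0s2, Trem1, Pglyrp1 and the interferon-inducible Ifit1bl. Endothelial-like cells were led by Plvap, Gpihbp1, Rbp7, Cdh5 and Adgrl4, and mural-like cells by Acta1, Tagln, Rgs5, Myh11 and Ppp1r14a. Acta1 is the skeletal muscle actin. T or NK-like cells were led by Ccl5, Gzmm, Prf1, Il17a and Nkg7, and keratinocyte-like cells by Krt17, Lgals7, Krt5, Stfa3 and Krt15. Mast or basophil-like cells were led by Mcpt1l1, Cma1, Cpa3, Tpsb2 and Tpsab1, adipocyte-like cells by Ca3, Retn, Adipoq, Pck1 and Cfd, and proliferating-like cells by Top2a, Cenpf, Ube2c, Mki67 and Tpx2.

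**Figure D1:**
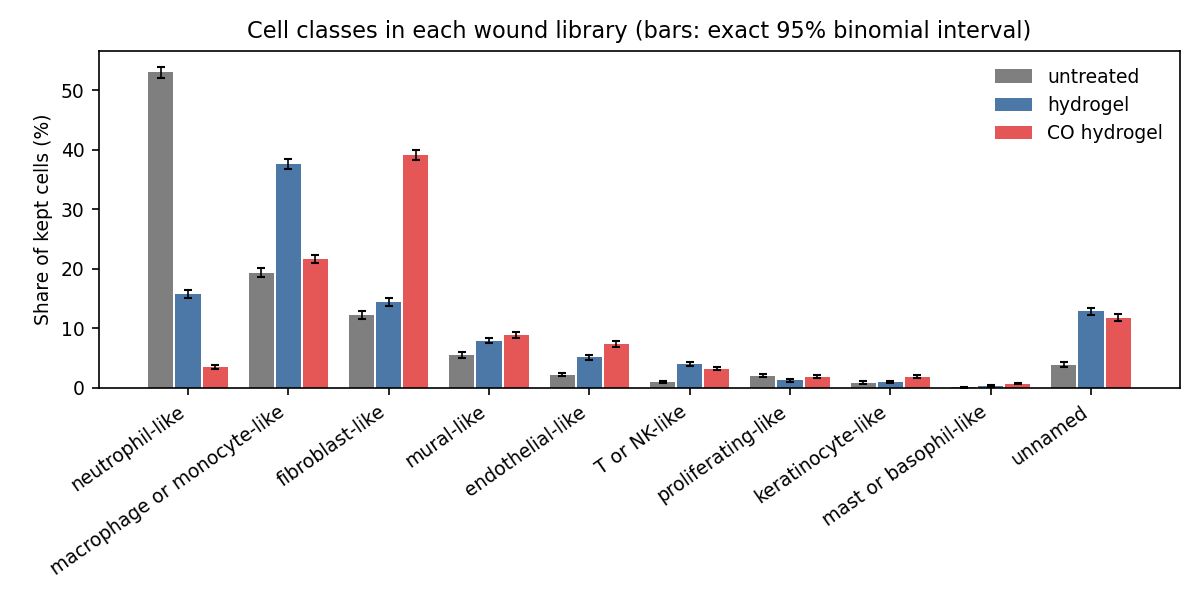
Share of kept cells (y axis, %) in each cell class (x axis) for the untreated (grey), hydrogel (blue) and CO hydrogel (red) libraries, 1 library each, with exact 95% binomial intervals. Neutrophil-like cells are 53.0% of the untreated library, macrophage or monocyte-like cells 37.6% of the hydrogel library and fibroblast-like cells 39.2% of the CO hydrogel library.

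The series title names Cxcl14-positive fibroblasts that accumulate after CO treatment, so Cxcl14, which encodes a chemokine made by epithelial and stromal cells, was read next. Cxcl14-positive fibroblast-like cells were a larger share of all cells in the CO hydrogel library, while the Cxcl14 level within fibroblast-like cells was lower there than in either of the others. They were 3.80% (3.44 to 4.18) of untreated, 4.18% (3.83 to 4.56) of hydrogel and 9.38% (8.87 to 9.90) of CO hydrogel cells. With every cell thinned to 1000 UMIs, these shares were 1.41% (1.19 to 1.66), 1.84% (1.60 to 2.10) and 3.82% (3.48 to 4.18). Of thinned cells that are not neutrophil-like they were 3.05%, 2.18% and 3.94%, so the CO hydrogel share was then nearer to the untreated one and the hydrogel share was the lowest. Within fibroblast-like cells the Cxcl14 level was 290.9 CPM (283.8 to 298.2) without treatment, 410.7 (402.5 to 419.0) with the hydrogel and 209.8 (205.7 to 214.0) with the CO hydrogel. The log2 ratio of CO hydrogel to hydrogel was -0.97 (-1.01 to -0.93), that of CO hydrogel to untreated -0.47 (-0.52 to -0.43), and that of hydrogel to untreated 0.50 (0.45 to 0.54).

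Among fibroblast-like cells, 31.2% of untreated, 29.1% of hydrogel and 23.9% of CO hydrogel cells had a Cxcl14 UMI. After thinning to 1000 UMIs the shares were 11.7% (9.97 to 13.7), 12.8% (11.3 to 14.6) and 9.42% (8.61 to 10.3), with 75, 78 and 149 shallower cells left out. As background, neutrophil-like cells, which should lack Cxcl14, gave 0.446%, 0.887% and 0.838% after thinning, at medians of 1987, 1812 and 1404 UMIs before it. T or NK-like cells gave 0 of 97, 0.647% and 0.781%. In the unthinned data their Cxcl14 levels were 0, 5.80 and 8.24 CPM, and those of neutrophil-like cells 4.49, 11.5 and 18.5. Cxcl14 was concentrated in few cells: the 1% of fibroblast-like cells with the most Cxcl14 UMIs held 40.9%, 33.7% and 42.2% of all Cxcl14 UMIs of the class.

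The fibroblast-like class was made of 4 clusters in different proportions. Cluster 0 held 31.1%, 45.8% and 56.1% of the class in the untreated, hydrogel and CO hydrogel libraries, cluster 6 held 23.4%, 43.3% and 20.6%, cluster 10 held 44.3%, 4.26% and 11.3%, and cluster 14 held 1.24%, 6.62% and 12.1%. Cxcl14 was itself a leading gene of cluster 14, beside Cilp, Eln and Thbs4. In that cluster Cxcl14 was at 3124, 4010 and 1321 CPM, and in cluster 0 at 930.9, 386.1 and 117.9. Cluster 6 went the other way between the hydrogel libraries, at 47.2, 11.2 (9.28 to 13.3) and 21.1 (18.4 to 24.1) CPM, and cluster 10 was at 43.5, 32.6 and 30.9. Against the class log2 ratio of 0.50 for hydrogel to untreated, clusters 0, 6 and 10 were lower with the hydrogel, cluster 10 with overlapping intervals. Cluster 14, with 16 untreated cells, was higher.

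**Figure D2:**
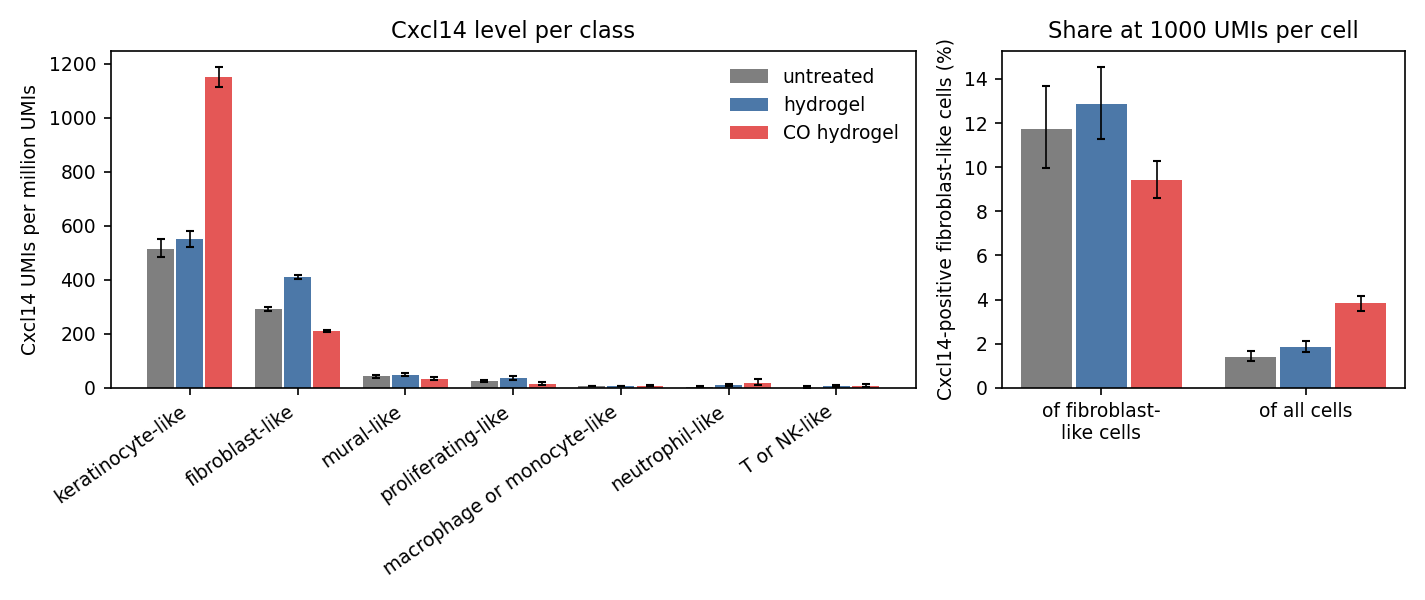
Left, Cxcl14 CPM (y axis) by class (x axis) in the untreated (grey), hydrogel (blue) and CO hydrogel (red) libraries with exact 95% Poisson intervals; right, the share (y axis, %) of fibroblast-like cells, and of all cells, that are Cxcl14-positive fibroblast-like cells at 1000 UMIs per cell, with exact 95% binomial intervals. Within fibroblast-like cells the CO hydrogel library has the lowest level, 209.8 CPM, and as a share of all cells the highest, 3.82%.

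To see what else Cxcl14-positive fibroblast-like cells expressed, they were compared with Cxcl14-negative ones in each library at 1000 UMIs per cell. Matrix genes were mostly lower in the positive cells of all 3 libraries, while higher complement and inflammatory genes did not hold in most of their members once the cluster mix was matched. There were 142, 213 and 453 positive cells, and of 4364 genes compared, 567 were higher and 959 lower in the positive cells of every library. Before thinning, 401, 505 and 1187 fibroblast-like cells had a Cxcl14 UMI. The negative group thus includes cells that lost their Cxcl14 UMIs in thinning. By the largest smallest difference, the genes higher included Cryab (mean log2 ratio 1.83 ± 0.39, SD, n = 3 libraries of different treatments), a small heat shock protein; Stmn2 (1.88 ± 0.48); Fgl2 (1.66 ± 0.24); Mgp (1.74 ± 0.30), an inhibitor of calcification; Gas6 (1.48 ± 0.04), a ligand of TAM receptors; Ccn5 (1.48 ± 0.15); Cygb (1.52 ± 0.23), cytoglobin; Ntrk2 (1.40 ± 0.14); and the complement gene C7 (1.54 ± 0.31). Those lower were Prss35 (-2.16 ± 0.52), Arhgap42 (-1.66 ± 0.14), Prdm1 (-1.97 ± 0.76), Fbn2 (-1.90 ± 0.75), Wnt4 (-2.21 ± 0.70), Hacd1 (-2.01 ± 0.68), Nt5dc2 (-1.53 ± 0.19), Col12a1 (-1.70 ± 0.55), Mpp6 (-1.35 ± 0.02) and Tpm2 (-1.47 ± 0.15).

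By the lists fixed in advance, 11 of 15 fibrillar collagen and wound matrix genes were lower with Cxcl14 in all 3 libraries and 2 were higher, with medians of -0.46 untreated, -0.51 hydrogel and -0.51 CO hydrogel. All 5 measured inflammatory cytokine genes and 5 of 7 complement and stromal chemokine genes were higher in all 3. Of 6 dermal papilla and Wnt genes 4 were lower in all 3 and 1 was higher, with medians of -0.30, -0.95 and -0.90. Fibroblast progenitor genes went both ways, 2 of 13 higher and 2 lower in all 3, with medians of -0.60, 0.25 and 0.08. The value of Hacd1 did not hold at another depth: with cells at 2000 UMIs its mean ratio was 0.05.

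Positive and negative cells lay in different clusters: cluster 14 held 4.93%, 31.9% and 48.8% of the positive cells but 0.748%, 3.25% and 8.58% of the negative ones in the same order of libraries. With the negative cells weighted to the clusters of the positive cells, a comparison chosen after seeing the data, 529 genes were higher and 708 lower in all 3 libraries. Of 15 fibrillar collagen and wound matrix genes 13 were then lower in all 3 and none higher, with medians of -0.49, -0.27 and -0.43. Only 1 of 5 inflammatory and 2 of 7 complement and stromal chemokine genes were then higher in all 3, and dermal papilla and Wnt medians turned to 0.14, 0.07 and 0.09. The mean ratios of Mgp, Ccn5 and Gas6 fell to 0.15, 0.20 and 0.27, that of Prss35 was -0.51, and those of Prdm1 and Tpm2 turned to 0.36 and 0.27. Those of Fbn2 (-1.50), Arhgap42 (-1.43), Mpp6 (-1.25), Ntrk2 (1.07) and Cryab (0.93) kept their sign in all 3 libraries. The untreated library had 7 positive and 8 negative cells in cluster 14.

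Within fibroblast-like cells the CO hydrogel and hydrogel libraries differed in progenitor and contractile genes, among others. The mix of clusters in the class differed too, and these lists were not read with the mix matched. Cluster 10 held 11.3% of the class with the CO hydrogel and 4.26% with the hydrogel, and cluster 6 held 20.6% and 43.3%. Most progenitor genes, such as Dpp4, Pi16 and Cd34, were higher with the CO hydrogel, contractile genes, such as Acta2 and Tagln, were lower, and collagen genes went both ways. Of 13 progenitor genes measured, 4 were at least 2-fold higher, none was 2-fold lower and 9 were within 2-fold, with a median log2 ratio of 0.71, above that of all 10000 random lists of matched expression but with an interval over members of -0.13 to 1.18. Dpp4 was at 80.4 against 19.8 CPM (log2 ratio 2.02, 1.88 to 2.17), Pi16 at 1.75, Clec3b at 1.18 and Cd34 at 1.09. All 10 contractile genes were lower, 4 of them at least 2-fold, with a median of -0.83 below all 10000 random lists: Cnn1 -1.49, Tagln -1.45, Acta2 -1.40 and Actg2 -1.07. Of these 10 genes, 6 were over 5 times higher in another class, and the other 4 had a median of -0.66. All 15 fibrillar collagen and wound matrix genes were within 2-fold, 8 of them above 0 and 7 below, with a median of 0.01 (-0.25 to 0.39 over members) above 4886 random lists, and this median turned to -0.03 with every cell weighted equally and -0.01 under the stricter cell filter.

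Inflammatory cytokines and chemokines had a median of -0.59 in this comparison, below all random lists, with 6 of 15 at least 2-fold lower, among them Nos2 (-4.12), Il1rn (-2.80), Il1b (-2.74) and Ccl3 (-2.21). Of the 15, 10 were over 5 times higher in another class, neutrophil-like cells differed 4.46-fold in share, and the remaining 5 had a median of -0.04. Hypoxia and glycolysis genes had a median of -0.27, above 4 random lists, with Ca9 at -1.34 and Slc2a1, the glucose transporter GLUT1, at -0.98. The heme oxygenase and antioxidant list, read because heme oxygenase makes CO, had a median of -0.11, above 719 random lists, with all 13 genes within 2-fold and Hmox1 at -0.73. Interferon response genes were all within 2-fold (median 0.28, above 9998). Dissociation and stress genes, which mark handling, had a median of -0.40, below all random lists. Other medians were 0.08 for growth factors, with Tgfb3 at 1.45 and Fgf10 at 1.01, 0.35 for proliferation, which turned to -0.19 with each library clustered by itself, -0.17 for dermal papilla and Wnt, with Bmp4 at 3.72, 0.15 for complement and stromal chemokines, with Ccl19 at -3.75 and C3 at -1.27, -0.08 for matrix proteases and inhibitors, with Mmp12 at -1.39 and Mmp13 at 1.18, -0.13 for adipogenic and -0.07 for housekeeping genes. All 8 adipogenic genes, 9 of 11 proliferation, 8 of 12 interferon response and 7 of 13 heme oxygenase and antioxidant genes were over 5 times higher in another class. Proliferation medians here and below leave out the proliferating-like class, named by markers such as Mki67 and Top2a. They depend on how that class was split off.

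Of 10641 genes with at least 100 UMIs, 209 were at least 2-fold higher with the CO hydrogel than with the hydrogel in fibroblast-like cells and 189 lower, a balance that turned to 1293 higher and 1483 lower with no minimum count and 0.5 counts added. In the other comparisons below that setting also raised both counts by over 1.5-fold, but more genes stayed higher than lower. The 10 highest ratios by the rule for named genes were those of Thbs4, a matricellular thrombospondin (log2 ratio 3.64, 3.37 to 3.92), Foxp2 (2.95), the steroid-metabolising Akr1c14 (2.94), Plcxd3 (2.37), Cck (2.24), Fez1 (2.15), Dpp4 (2.02), Pamr1 (1.95), Efemp1, encoding fibulin-3 (1.93), and Plac9 (1.86). Thbs4 was at 63.6 against 5.11 CPM and Efemp1 at 239.5 against 62.8. Among the 10 lowest were Cxcl6, a neutrophil-attracting chemokine (-2.31, -2.37 to -2.25), Olfm2 (-2.26), Wt1 (-2.17), Trh (-2.03), Prg4, encoding lubricin (-1.95), Kank4 (-1.91), Cyp11b3 (-1.87), the complement regulator Cfi (-1.80) and Epha3 (-1.68). Cxcl6 was at 75.4 against 374.2 CPM.

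Against the untreated wound, fibroblast-like cells of the CO hydrogel wound had higher interferon response genes and lower inflammatory and hypoxia genes, while progenitor genes went both ways. Of 12 interferon response genes, 9 were at least 2-fold higher and none 2-fold lower, with a median of 1.23 above all 10000 random lists: Rsad2 3.91, Mx2 3.31, Cxcl10 2.97 and Isg15 1.44. Of the 12, 8 were over 5 times higher in another class, and the other 4 had a median of 1.12. Of 15 inflammatory genes 8 were at least 2-fold lower and 1 higher, with a median of -1.02 below all random lists: Nos2 -4.78, Ccl3 -3.76 and Cxcl2 -3.36, and -0.73 over the 5 not higher elsewhere. In untreated neutrophil-like cells Nos2, Ccl3 and Cxcl2 were at 4147, 14050 and 70043 CPM, and neutrophil-like cells differed 15.1-fold in share. Free RNA therefore stays open for the ratios of these 3 genes. Of 14 hypoxia and glycolysis genes 5 were at least 2-fold lower, with a median of -0.78 below all random lists: Egln3 -1.46, Slc2a1 -1.41, Bnip3 -1.39 and Ldha -1.07. Of 13 progenitor genes 5 had a ratio above 0 and 8 below it, with a median of -0.83 below all random lists but an interval over members of -1.29 to 0.50. Of these genes 4 were at least 2-fold lower and Col15a1 (1.62) was higher: Cd55 -1.58, Anxa3 -1.35, Dpp4 -1.29 and Fbn1 -1.09. Cluster 10, with the progenitor-list genes Fbn1 and Mfap5 among its leading genes, held 44.3% of untreated and 11.3% of CO hydrogel fibroblast-like cells. The lists were not read with the mix of clusters matched.

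Contractile genes had a median of 0.44 in fibroblast-like cells of the CO hydrogel against the untreated library, above 9900 random lists, with Actg2 (1.17) the one at least 2-fold higher and 6 of the 10 higher elsewhere. Fibrillar collagen and wound matrix genes had a median of 0.09, which turned to -0.05 with TMM factors and -0.08 with every cell weighted equally. Of them Postn, encoding periostin, was 2-fold higher (1.46) and Fn1, fibronectin, was at -0.89. Matrix proteases and inhibitors had a median of 0.33, with 5 of 15 at least 2-fold higher, among them Mmp3 (3.46), Mmp13 (2.30) and Mmp12 (2.16), and 3 lower, among them Timp1 (-1.52), and 0.16 over the 8 genes not higher elsewhere. Growth factors had a median of 0.58, above 9999 random lists, with Fgf10 (2.41), Angpt1 (1.31) and Igf1 (1.19) among 6 at least 2-fold higher and Ereg (-1.73) lower. The other medians were 0.56 for dissociation and stress, 0.58 for dermal papilla and Wnt, with Bmp4 at 1.47, -0.43 for proliferation, which was -2.92 with each library clustered by itself, -0.25 for heme oxygenase and antioxidant, with Slc7a11 at -1.50, 0.18 for adipogenic, with all 8 genes and 9 of 11 proliferation genes higher elsewhere, and 0.01 for complement and stromal chemokines and 0.05 for housekeeping genes, both of which turned negative with TMM factors (-0.12 and -0.08), and the last also with every cell weighted equally (-0.18).

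Of 10504 genes, 631 were at least 2-fold higher in fibroblast-like cells of the CO hydrogel than of the untreated library and 281 lower, a split of 69.2% higher that became 515 and 353, or 59.3%, with TMM factors, which moved all ratios of this pair by 0.14. The 10 highest were Plcxd3 (5.98, 4.42 to 8.26, against 3 untreated UMIs), the lipid transporter Abca8a (5.56), the collagen VI chain gene Col6a6 (5.25), Cilp, a matrix protein of cartilage (4.35), Capn6 (4.15), the calcium-binding parvalbumin gene Pvalb (3.83), the glypican gene Gpc3 (3.77), Ptn, the growth factor pleiotrophin (3.43), Etv1 (3.35) and the interferon-induced Mx2 (3.31). Ptn was at 770.8 against 71.6 CPM. The 10 lowest were Hoxc10, a transcription factor gene of body position (-6.95, -9.24 to -5.38, on 3 CO hydrogel UMIs), Foxq1 (-4.62), Pcp4 (-3.82), Nt5c1b (-3.68), Lcn2, an iron-sequestering protein induced in inflammation (-3.57), Cdhr5 (-3.34), the secreted phospholipase gene Pla2g2a (-3.34), Msln, mesothelin (-2.93), Prg4 (-2.90) and Mfap3l (-2.84). Lcn2 was at 63.4 against 751.3 CPM. With every cell weighted equally, 12 of these 20 ratios moved by over 1.5-fold and none turned: Pvalb came to 1.88 and Hoxc10 to -4.14.

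Fibroblast-like cells of the hydrogel library, without CO, also differed from those of the untreated library, with higher contractile and interferon genes and lower progenitor genes. Of 10 contractile genes 7 were at least 2-fold higher and none lower, with a median of 1.29 above all 10000 random lists: Actg2 2.23, Tagln 1.46, Acta2 1.36 and Cnn1 1.32. The 4 not higher in another class had a median of 1.21. Of 13 progenitor genes 9 were at least 2-fold lower and 1, Col15a1 (2.03), was higher, with a median of -1.39 below all random lists: Dpp4 -3.31, Fbn1 -1.85, Anxa3 -1.77 and Pi16 -1.74. Of 12 interferon response genes 6 were at least 2-fold higher and none lower, with a median of 0.99 above all random lists and Rsad2 at 3.97, and 1.06 over the 4 not higher in another class. Cluster 10, led by Tnfrsf11b, Gap43 and the progenitor-list genes Fbn1, Mfap5 and Gfpt2, held 44.3% of untreated and 4.26% of hydrogel fibroblast-like cells. The mix of clusters was not matched for this pair either.

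Inflammatory genes had a median of -0.64 in fibroblast-like cells of the hydrogel against the untreated library, and hypoxia and glycolysis genes -0.55, both below all random lists, with Bnip3 at -1.53. Of the 14 inflammatory genes, 9 were over 5 times higher in another class, neutrophil-like cells differed 3.38-fold in share, and the other 5 had a median of -0.45. Dissociation and stress genes had a median of 0.88, above all random lists, with Hspa1b at 1.56, Dnajb1 at 1.39 and Fos at 1.14. Proliferation genes had a median of -0.74, below all random lists, which was -2.68 with each library clustered by itself, and 9 of the 11 were over 5 times higher in another class. Proliferating-like cells were named apart, so this median leaves them out and does not measure how many fibroblasts divided. Matrix proteases and inhibitors had a median of 0.57, with Mmp12 (3.56), Mmp3 (2.91) and Timp3 (1.60) higher, but 0.11 over the 8 genes not higher elsewhere. The other medians were 0.34 for fibrillar collagen and wound matrix, with Fn1 at -1.61, 0.58 for growth factors, 0.54 for dermal papilla and Wnt, with Bmp4 at -2.25, 0.62 for adipogenic, with all 8 genes higher elsewhere, and -0.14 for heme oxygenase and antioxidant, which turned to 0.05 with no doublets removed. Complement and stromal chemokines (0.12) and housekeeping genes (0.00) both turned negative with TMM factors, to -0.04 and -0.16, and with every cell weighted equally, to -0.09 and -0.06.

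Of 9820 genes, 473 were at least 2-fold higher in hydrogel than in untreated fibroblast-like cells and 221 lower, which became 344 and 320 with TMM factors, moving the share of higher genes from 68.2% to 51.8% with a shift of 0.17. The 10 highest were Abca8a (4.41, 3.46 to 5.56), Col6a6 (4.30), Olfm2 (3.85), Cilp (3.73), Nsg2 (3.16), C7 (3.05), Pvalb (3.03), the growth factor gene Fgf1 (3.01), Reln, encoding reelin (2.91), and Nsg1 (2.88). The 10 lowest were the steroid-metabolising Akr1c3 (-4.59, -5.25 to -4.01), Cdhr5 (-3.85), Hoxc10 (-3.63), Dpp4 (-3.31), Plac9 (-2.88), Lgi3 (-2.87), the potassium channel gene Kcnq5 (-2.87), Fez1 (-2.81), Thbs4 (-2.77) and Abca4 (-2.69). C7 was at 160.5 against 19.4 CPM and Dpp4 at 19.8 against 196.7. With every cell weighted equally, 10 of these 20 ratios moved by over 1.5-fold and none turned, Pvalb coming to 0.94.

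Macrophage or monocyte-like cells of the CO hydrogel and hydrogel libraries differed in genes of resident macrophages, hypoxia and interferon. Of 16 alternatively activated or resident macrophage genes, 10 were at least 2-fold higher with the CO hydrogel, 2 were lower and 4 were within 2-fold, with a median of 1.82 above all 10000 random lists, which was 0.28 (-0.11 to 0.70 over members) with clusters weighted as in the hydrogel library. Cd163, a scavenger receptor for hemoglobin, was at 373.1 against 50.9 CPM (2.87, 2.80 to 2.95), the hyaluronan receptor gene Lyve1 at 2.86, the lectin gene Clec10a at 2.85 and Igf1 at 2.15, while Arg1, arginase 1, was at -2.28 and Spp1, osteopontin, at -1.07. Of 13 hypoxia and glycolysis genes 8 were at least 2-fold lower and none higher, with a median of -1.04 below all random lists: Ankrd37 -2.59, Egln3 -2.19, Slc2a1 -1.69 and Vegfa -1.61. Of 12 interferon response genes 2, Oas1a (1.45) and Mx2 (1.02), were at least 2-fold higher and 1 was lower, with a median of 0.77 above all random lists but an interval over members of -0.06 to 0.97. Cluster 7, whose leading genes include Cd163, F13a1 and Clec10a of the resident list, held 39.8% of the class with the CO hydrogel, 6.91% with the hydrogel and 13.6% untreated, and cluster 3, led by Spp1 and Cxcl11, held 14.8%, 42.0% and 16.6%.

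Inflammatory genes had a median of -0.42 (-1.17 to 0.17 over members) in this macrophage comparison, below all random lists, but went both ways: 6 of 15 were at least 2-fold lower, such as Csf3 (-3.33) and Nos2 (-2.61), and 3 higher, Ccl2 (1.47), Ccl7 (1.45) and Ccl4 (1.12). Heme oxygenase and antioxidant genes had a median of -0.53, below all random lists, with Slc7a11, the cystine transporter, at -1.55, Txn1 at -1.45 and Sod2 at -1.21, while Hmox1 was at 0.08. Matrix proteases and inhibitors had a median of 0.45, complement and stromal chemokines 0.53 and growth factors 0.41, but 11 of 13, 6 of 9 and 7 of 13 of these genes were over 5 times higher in another class. Without such genes the last 2 medians were -0.73 and -1.19, and that of growth factors was -0.02 under the stricter cell filter. The other medians were 0.09 for class II antigen presentation, 0.77 for dermal papilla and Wnt, with 6 of 8 genes higher elsewhere, 0.11 for proliferation, with 10 of 11 genes higher elsewhere, which turned to -0.09 with every cell weighted equally, 0.22 for dissociation and stress, -0.44 for adipogenic genes, which turned to 0.01 with no doublets removed, and 0.01 for housekeeping genes, which turned to -0.03 with TMM factors and -0.01 with every cell weighted equally.

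Of 9387 genes, 402 were at least 2-fold higher with the CO hydrogel than with the hydrogel in macrophage or monocyte-like cells and 257 lower. The 10 highest were the asialoglycoprotein receptor gene Asgr2 (3.42, 3.29 to 3.54), Pdgfc (3.17), Alox5 and Ltc4s, which encode enzymes of leukotriene synthesis (3.00 and 2.98), the transporter gene Slco2b1 (2.92), Cd163, Lyve1, Clec10a, Atp1b1 (2.70) and Fcgrt, the neonatal Fc receptor gene (2.65). The 10 lowest were Ptges, a prostaglandin E synthase (-3.67, -4.01 to -3.35), the interferon-induced chemokine gene Cxcl11 (-3.64), the arginine transporter gene Slc7a2 (-3.60), Fcrla (-3.51), Csf3, encoding G-CSF (-3.33), Slc47a1 (-3.10), Met, the receptor of hepatocyte growth factor (-2.79), MGC105649 (-2.62), Ass1, argininosuccinate synthase (-2.54), and Slamf6 (-2.49). Ptges was at 5.40 against 68.9 CPM and Cxcl11 at 31.6 against 394.4. With every cell weighted equally, 5 of these 20 ratios moved by over 1.5-fold and none turned, and Slamf6 was at -1.22 under the stricter cell filter.

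Compared with the untreated wound, macrophage or monocyte-like cells of the CO hydrogel wound had lower inflammatory and hypoxia genes and higher interferon genes. Of 15 inflammatory genes 10 were at least 2-fold lower and 1, Ccl4 (1.01), was higher, with a median of -1.42 below all 10000 random lists: Csf3 -5.90, Cxcl3 -3.28, Nos2 -3.26 and Ccl3 -2.15. Of 13 hypoxia and glycolysis genes 7 were at least 2-fold lower and none higher, with a median of -1.20 below all random lists: Ankrd37 -2.10, Vegfa -1.81, Slc2a1 -1.78 and Ldha -1.63. Of 12 interferon response genes 8 were at least 2-fold higher and none lower, with a median of 1.49 above all random lists: Rsad2 2.60, Ifit2 2.57, Mx2 2.56 and Cxcl10 1.95. Of 16 resident macrophage genes 7 were at least 2-fold higher, such as Igf1 (2.02), Clec10a (1.67), Gas6 (1.64) and Stab1 (1.39), and 2 lower, Arg1 (-3.33) and Spp1 (-1.15), with a median of 0.98 above all random lists but an interval over members of -0.60 to 1.39. Cluster 11, led by Spp1, Csf3 and Ereg, held 32.7% of the class untreated, 10.7% with the hydrogel and 1.28% with the CO hydrogel.

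Growth factors in this comparison had a median of -0.42, with Ereg (-3.05) and Areg (-2.55), ligands of the epidermal growth factor receptor, lower, and Igf1 (2.02) and Hbegf (1.07) higher. Proliferation genes had a median of 0.78, which turned to -0.38 with each library clustered by itself, and 10 of 11 were over 5 times higher in another class. Class II antigen presentation genes were all within 2-fold, with a median of 0.35. This median leaves out the unnamed cluster 15, which has class II genes among its leading genes. The other medians were -0.12 for heme oxygenase and antioxidant, with Hmox1 at -0.02 and the biliverdin reductase gene Blvrb at 1.56, 0.25 for dissociation and stress, 0.52 for matrix proteases and inhibitors, with 11 of 13 genes higher elsewhere, and 1.24 for dermal papilla and Wnt, with 5 of 7 genes higher elsewhere. Medians of 0.58 for complement and stromal chemokines and 0.28 for adipogenic genes were -0.11 and -0.40 without genes higher in another class, and that of housekeeping genes, 0.15, was -0.05 with TMM factors.

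Of 8455 genes, 512 were at least 2-fold higher in macrophage or monocyte-like cells of the CO hydrogel than of the untreated library and 255 lower, a split of 66.8% higher that became 333 and 368, or 47.5%, with TMM factors, which moved all ratios of this pair by 0.20. The 10 highest were Dtnb (2.71, 2.24 to 3.22), Ifit2 (2.57), Mx2 (2.56), the metallothionein genes Mt1 (2.31) and Mt2A (2.14), the glucagon receptor gene Gcgr (2.28), Tfrc, the transferrin receptor gene (2.21), Atp1b1 (2.20), Slco2b1 (2.18) and Itgb5 (2.16). The 10 lowest were Csf3 (-5.90, -6.23 to -5.59), Thbs1, thrombospondin 1 (-4.01), Ptges (-3.50), Arg1 (-3.33), Cxcl3 (-3.28), Slc7a2 (-3.27), Dpys (-3.12), Ereg (-3.05), Met (-2.85) and Thbd, thrombomodulin (-2.75). Cxcl3 was at 1640 against 15890 CPM and Thbs1 at 56.8 against 914.6. With every cell weighted equally, 6 of these 20 ratios moved by over 1.5-fold and none turned, Mt1 coming to 1.21.

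With the hydrogel alone, macrophage or monocyte-like cells had higher interferon genes and lower inflammatory and resident macrophage genes than in the untreated wound. Of 12 interferon response genes 6 were at least 2-fold higher and none lower, with a median of 1.06 above all 10000 random lists: Rsad2 2.66, Ifit2 1.82 and Mx2 1.54. Of 15 inflammatory genes 8 were at least 2-fold lower and none higher, with a median of -1.03 below all random lists: Csf3 -2.57, Cxcl3 -2.20 and Ccl3 -1.72. Of 16 resident macrophage genes 8 were at least 2-fold lower, such as Lyve1 (-3.04), Cd209f (-1.77) and Cd163 (-1.71), and 2, Gpnmb (1.22) and Trem2 (1.05), higher, with a median of -0.99 below all random lists. Hypoxia and glycolysis genes were all within 2-fold, with a median of -0.09. Heme oxygenase and antioxidant genes had a median of 0.41, above 9990 random lists, with Blvrb (1.03) the one at least 2-fold higher and Hmox1 at -0.10.

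The other medians of hydrogel against untreated macrophage or monocyte-like cells were 0.22 for class II antigen presentation, whose regulator Ciita was at 1.30, -0.30 for growth factors, 0.44 for complement and stromal chemokines, 0.17 for dermal papilla and Wnt, 0.58 for proliferation, which turned to -0.42 with each library clustered by itself, with 6 of 9, 7 of 9 and 10 of 11 genes of these 3 lists higher elsewhere, -0.09 for dissociation and stress, which turned to 0.12 under the stricter cell filter, and 0.19 for housekeeping genes. Matrix proteases and inhibitors (0.14, with 11 of 13 genes higher elsewhere) and adipogenic genes (0.16) turned to -0.03 and -0.01 with TMM factors. Of 9301 genes, 428 were at least 2-fold higher and 202 lower, which became 310 and 269 with TMM factors, moving the share of higher genes from 67.9% to 53.5% with a shift of 0.17. The 10 highest were the metallothionein genes Mt1 (3.86, 3.83 to 3.89), Mt1m (3.80) and Mt2A (3.54), Cxcl11 (3.53), Fcrla (3.15), MGC105567 (3.08), Slamf6 (3.01), MGC108823 (2.94), Il15ra (2.84) and Irgm (2.75). The 10 lowest were Lyve1 (-3.04), Arhgap8 (-2.83), Thbs1 (-2.74), Csf3 (-2.57), Asgr2 (-2.49), the neuregulin gene Nrg1 (-2.40), Rnase2 (-2.39), Fmo5 (-2.29), Cxcl3 (-2.20) and the complement gene C6 (-2.09). Mt1 was at 9697 against 668.6 CPM. With every cell weighted equally, 6 of these 20 ratios moved by over 1.5-fold and none turned, Mt1m coming to 1.88.

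**Figure D3:**
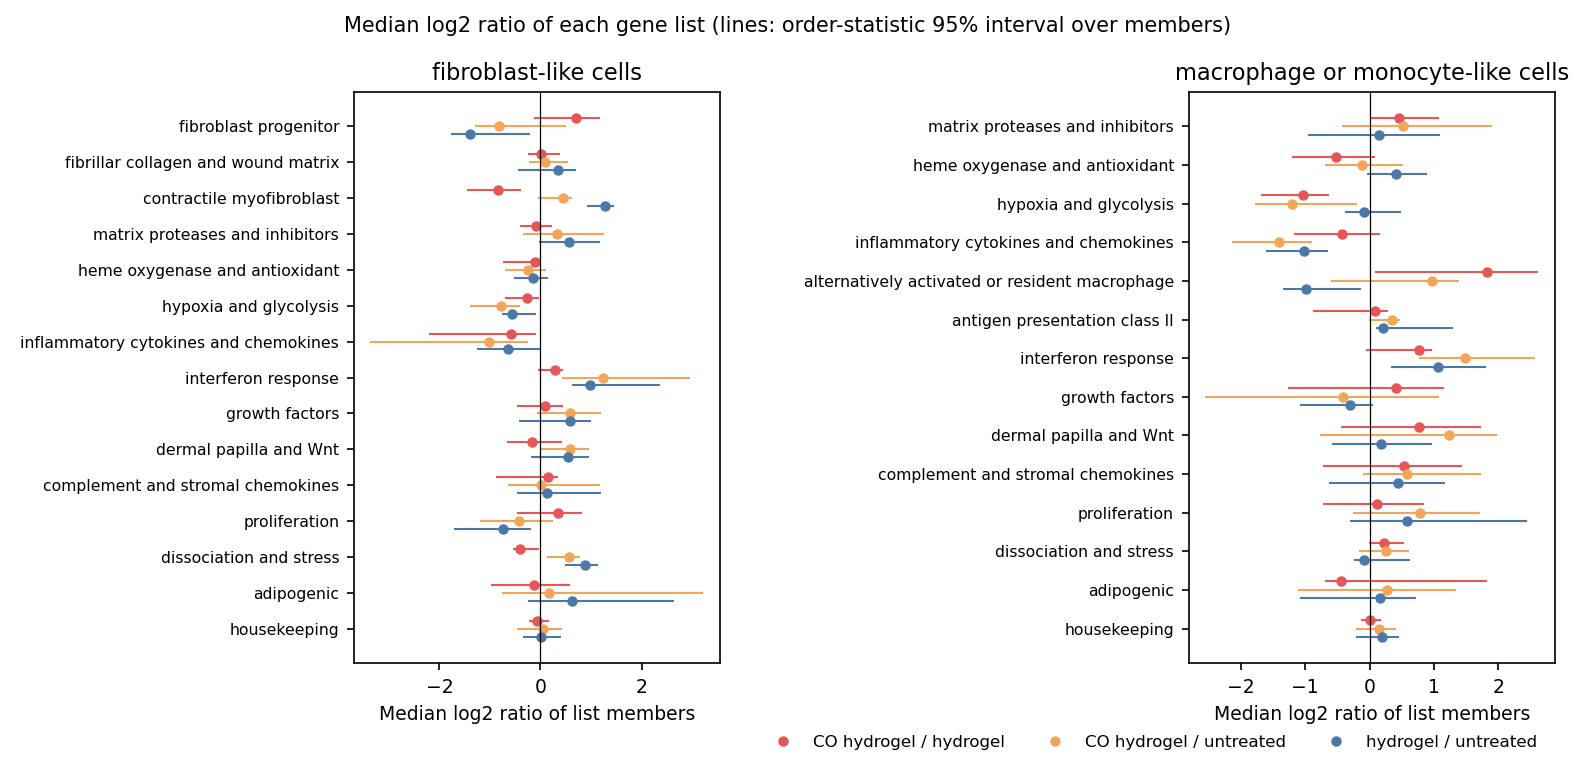
Median log2 ratio (x axis) of each gene list (y axis) in fibroblast-like (left) and macrophage or monocyte-like cells (right) for CO hydrogel against hydrogel (red), CO hydrogel against untreated (orange) and hydrogel against untreated (blue); lines are exact order-statistic 95% intervals over the list's members, which are not replicates. Resident macrophage genes lie at 1.82 for CO hydrogel against hydrogel and -0.99 for hydrogel against untreated, and contractile genes of fibroblast-like cells at -0.83 and 1.29.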

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

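All tests in this part were chosen only after the result was seen, except the weighting of macrophage or monocyte-like clusters, whose prediction was written first. With 1 library per group, CO release cannot be separated from any other difference between the specimens.

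Some gene lists had medians of opposite sign in fibroblast-like and macrophage or monocyte-like cells, and these differences were not tested. Those named here lay in the outer 2.5% of random lists in both classes and kept their sign without genes over 5 times higher in another class. In each the interval over members spanned 0 in at least 1 of the classes. Other lists with opposite signs did not meet these conditions, such as dissociation and stress genes for hydrogel against untreated (0.88 and -0.09). For CO hydrogel against hydrogel, dissociation and stress genes were at -0.40 in fibroblast-like and 0.22 in macrophage or monocyte-like cells, a difference of -0.63. For CO hydrogel against untreated, growth factors were at 0.58 and -0.42, a difference of 1.00, and for hydrogel against untreated at 0.58 and -0.30, a difference of 0.88. For hydrogel against untreated, heme oxygenase and antioxidant genes were at -0.14 and 0.41, a difference of -0.56, and the fibroblast-like value turned to 0.05 with no doublets removed.

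Cells in 7 clusters of no class, of which cluster 13 alone enters a comparison of the report, as an alternative, were a larger share of all cells in a treated library than in the untreated one, whose large neutrophil-like share lowers its other shares. Cluster 13, led by the interferon-induced Rsad2 and Isg15 and by Acod1, was 7.57% of hydrogel cells against 1.01% untreated and 0.0869% CO hydrogel. Its marker score was highest for neutrophils, 0.584 with 6 markers detected, and it was left unnamed for few UMIs and no leading neutrophil marker by a rule chosen after the data were seen. Counted as neutrophil-like, it raises that share of the hydrogel library from 15.7% to 23.2%. Cluster 15, led by Hba-a2, Ccl17 and Clec10a with class II genes such as Cd74, was 3.83% of CO hydrogel against 0.903% of hydrogel and 1.20% of untreated cells. Its marker score was highest for macrophages or monocytes, 0.42 with 11 markers detected. It was left unnamed because its leading genes held more markers of another class. The macrophage or monocyte-like shares and class II medians above therefore leave it out. Cluster 16, led by Myog, Cpa1 and Actc1, was 3.16% against 1.43% and 0.692% in the same order. Cluster 22, with Cd7, Blnk and Siglech among its leading genes, was 1.58% against 0.265% untreated, with 200 CO hydrogel, 181 hydrogel and 28 untreated cells. Cluster 23, led by Ccl22, Cd207 and Tbc1d4, was 0.964% of CO hydrogel, 0.787% of hydrogel and 0.597% of untreated cells, and cluster 25, led by Acp5 and Ctsk, genes of bone-resorbing cells, and by Mt3, was 0.814% against 0.646% and 0.104%. Cluster 26, led by Ccl21, Acta1 and Krt15, genes of 3 cell types, was 1.32% against 0% and 0.00948%. Beside Acta1, the skeletal muscle markers Ckm and Mylpf were also among its leading genes, and 167 of its 168 cells were from the CO hydrogel library.

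The Cxcl14 level of fibroblast-like cells was lower with the CO hydrogel than with the hydrogel. With every cell at 1000 UMIs the log2 ratio was -0.85 (-0.97 to -0.72). This argues against a greater weight of cells with many UMIs as the source of the lower level. The CPM level is already scaled to UMIs, so thinning cannot decide on other effects of depth, which stay open. The 1% of cells with the most Cxcl14 UMIs are argued against as the source of the lower level by -1.17 (-1.22 to -1.12) without them. A wider group of high cells stays open. Cells with at least 10 Cxcl14 UMIs, at unmatched depth, were 9.79% of hydrogel and 4.25% of CO hydrogel fibroblast-like cells. A different mix of fibroblast-like clusters is argued against by -1.55 with clusters weighted as in the hydrogel library. Cxcl14 itself was left out of the genes that made the clusters. Cluster 6 alone went the other way, from 11.2 to 21.1 CPM. CO release, the specimen and the animals stay open, as untested.

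The neutrophil-like share was higher in the untreated than in the CO hydrogel library. Barcodes of few UMIs are argued against by a ratio of 17.1 between the shares under the stricter cell filter. For barcodes of free RNA alone, the ratio of inflammatory to collagen UMIs was read, markers left out. Relative to T or NK-like cells, whose collagen should be free RNA, the smallest value of the 3 libraries was 11.3 (10.2 to 12.4). The inflammatory genes were open to use in the clustering, and Cxcl3 and Ccl3 were leading genes of neutrophil-like cluster 1. A high ratio was thus partly built in, so this value cannot decide and the explanation stays open. Cells of other types than macrophages carrying free RNA are argued against by the genes of those classes. Their median levels in neutrophil-like cells, as fractions of those in their own class, had a largest sum of 0.105 (upper ends of the intervals 0.195) over the 3 libraries. Macrophages carrying free RNA stay open, with a fraction of up to 0.197 (0.079 to 0.778), too wide an interval to decide, and this split was made after the values were seen. More blood in the untreated specimen stays open: hemoglobin was 1.06 times as high as in the CO hydrogel library (598.6 against 564.1 CPM), and the red cells were lysed per the labels, which makes hemoglobin a poor measure of blood. The treatment stays open, as untested.

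Resident macrophage genes were higher in macrophage or monocyte-like cells of the CO hydrogel than of the hydrogel library. With clusters weighted as in the hydrogel library the list median was 0.28 (-0.11 to 0.70), so a different mix of clusters stays open as an account of most of the difference, although these genes were among those that made the clusters. More surrounding skin in the CO hydrogel specimen stays open too: mast and keratinocyte-like cells were 2.65% of cells that are not neutrophil-like, against 1.45%, a ratio of 1.82. A change in the cells with CO release was not tested apart from these.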

How the results depend on the processing

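All values here come from alternatives fixed before the data were examined, except leaving out genes over 5 times higher in another class, leaving neutrophil-like cells out of the total, counting cluster 13 as neutrophil-like and weighting Cxcl14-negative cells by cluster, which were chosen after seeing the data. Where a value below differs from the report, the cause was not tested. No paired analysis was possible because each group has 1 library.

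Of the 168 class shares recomputed under an alternative, 85 stayed within their counting interval and 83 moved beyond it. Of 57 Cxcl14 values 30 did not move beyond their interval, and the direction of the Cxcl14 ratio in fibroblast-like cells held under every alternative run for each of the 3 pairs. None of these alternatives matched the mix of fibroblast-like clusters, which was weighted for CO hydrogel against hydrogel alone. For hydrogel against untreated, clusters 0, 6 and 10 went against the ratio of the class, so its direction may depend on that mix. Of 98 counts of genes 83 stayed within 1.5-fold. Of 636 list medians in the classes compared, 612 stayed within their interval over members, 15 moved beyond it, and 9 that lay in the outer 2.5% of random lists changed sign. Counting all medians wherever they lay, 41 changed sign, 31 of them within their interval. Of 720 values of named genes 513 stayed within their interval, 207 moved beyond it and 0 turned. Of 140 values of genes going with Cxcl14, 68 did not move, 69 moved and 3, those of Hacd1, Prdm1 and Tpm2, turned. Whole lists with under 6 measured members were not recomputed, since so few members give no 95% interval, and medians left with under 6 after genes are left out have none.

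Under the stricter cell filter, the fibroblast-like share was 17.8% untreated, 16.1% hydrogel and 50.1% CO hydrogel and the mural-like share was 7.99% CO hydrogel. The endothelial-like share was 2.96% untreated and the keratinocyte-like share was 1.60% CO hydrogel. The macrophage or monocyte-like share was 23.9% untreated, 36.2% hydrogel and 20.3% CO hydrogel and the neutrophil-like share was 42.6% untreated, 17.9% hydrogel and 2.49% CO hydrogel. The T or NK-like share was 1.73% CO hydrogel and the adipocyte-like share was 0% hydrogel and 0% CO hydrogel. The proliferating-like share was 3.52% untreated and 2.41% CO hydrogel and the unnamed share was 1.39% untreated, 9.32% hydrogel and 3.83% CO hydrogel. The Cxcl14 log2 ratio in fibroblast-like cells was -0.37 for CO hydrogel against untreated and 0.60 for hydrogel against untreated. Cxcl14-positive fibroblast-like cells were 1.97% untreated and 4.71% CO hydrogel of all cells. Antigen presentation class II genes in macrophage or monocyte-like cells had a median of 0.38 for CO hydrogel against hydrogel and 0.68 for CO hydrogel against untreated. Growth factors genes in macrophage or monocyte-like cells had a median of -0.021 for CO hydrogel against hydrogel.

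With no doublets removed, the fibroblast-like share was 10.1% untreated, 13.4% hydrogel and 35.7% CO hydrogel and the endothelial-like share was 3.15% untreated, 6.94% hydrogel and 9.76% CO hydrogel. The keratinocyte-like share was 1.16% hydrogel and 2.50% CO hydrogel and the macrophage or monocyte-like share was 35.3% hydrogel and 22.6% CO hydrogel. The neutrophil-like share was 20.7% hydrogel and the T or NK-like share was 4.62% hydrogel. The adipocyte-like share was 0% hydrogel and 0% CO hydrogel and the proliferating-like share was 0.658% hydrogel and 1.54% CO hydrogel. The unnamed share was 8.71% hydrogel. The Cxcl14 log2 ratio in fibroblast-like cells was -0.54 for CO hydrogel against untreated and 0.41 for hydrogel against untreated. Heme oxygenase and antioxidant genes in fibroblast-like cells had a median of 0.054 for hydrogel against untreated. Adipogenic genes in macrophage or monocyte-like cells had a median of 0.013 for CO hydrogel against hydrogel. Antigen presentation class II genes in macrophage or monocyte-like cells had a median of 0.49 for CO hydrogel against untreated.

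At resolution 2, the fibroblast-like share was 11.5% untreated and the mural-like share was 6.88% hydrogel and 7.69% CO hydrogel. The endothelial-like share was 4.40% hydrogel and the macrophage or monocyte-like share was 36.0% hydrogel and 24.0% CO hydrogel. The neutrophil-like share was 14.1% hydrogel and the unnamed share was 5.35% untreated, 18.3% hydrogel and 10.9% CO hydrogel. Antigen presentation class II genes in macrophage or monocyte-like cells had a median of 0.30 for CO hydrogel against hydrogel and 0.52 for CO hydrogel against untreated.

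With each library clustered by itself, the fibroblast-like share was 13.1% untreated and the endothelial-like share was 2.89% untreated and 11.7% CO hydrogel. The macrophage or monocyte-like share was 20.7% untreated, 35.6% hydrogel and 22.4% CO hydrogel and the neutrophil-like share was 12.1% hydrogel. The mast or basophil-like share was 0% untreated and the adipocyte-like share was 0% hydrogel and 0% CO hydrogel. The proliferating-like share was 0.474% untreated and 0.903% hydrogel and the unnamed share was 1.29% untreated, 18.8% hydrogel and 6.28% CO hydrogel. The Cxcl14 log2 ratio in fibroblast-like cells was -0.35 for CO hydrogel against untreated and 0.61 for hydrogel against untreated. Proliferation genes in fibroblast-like cells had a median of -0.19 for CO hydrogel against hydrogel, -2.92 for CO hydrogel against untreated and -2.68 for hydrogel against untreated. Antigen presentation class II genes in macrophage or monocyte-like cells had a median of 0.37 for CO hydrogel against hydrogel and 0.64 for CO hydrogel against untreated. Adipogenic genes in macrophage or monocyte-like cells had a median of 0.062 for CO hydrogel against hydrogel. Proliferation genes in macrophage or monocyte-like cells had a median of -0.38 for CO hydrogel against untreated and -0.42 for hydrogel against untreated.

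Among cells that are not neutrophil-like, an alternative chosen after seeing the data, the fibroblast-like share was 25.9% untreated, 17.1% hydrogel and 40.6% CO hydrogel and the mural-like share was 11.7% untreated and 9.39% hydrogel. The endothelial-like share was 4.66% untreated and 6.05% hydrogel and the keratinocyte-like share was 1.88% untreated. The macrophage or monocyte-like share was 41.1% untreated, 44.6% hydrogel and 22.5% CO hydrogel and the T or NK-like share was 1.996% untreated and 4.65% hydrogel. The proliferating-like share was 4.34% untreated and 1.47% hydrogel and the unnamed share was 8.27% untreated and 15.2% hydrogel. Cxcl14-positive fibroblast-like cells were 3.05% untreated and 2.18% hydrogel of those at 1000 UMIs.

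With cluster 13 counted as neutrophil-like, an alternative chosen after seeing the data, the neutrophil-like share was 54.0% untreated and 23.2% hydrogel and the unnamed share was 2.87% untreated and 5.27% hydrogel.

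With every cell weighted equally, the Cxcl14 log2 ratio in fibroblast-like cells was -0.78 for CO hydrogel against hydrogel, -0.33 for CO hydrogel against untreated and 0.44 for hydrogel against untreated.

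With TMM factors, the Cxcl14 log2 ratio in fibroblast-like cells was -0.61 for CO hydrogel against untreated and 0.33 for hydrogel against untreated. Antigen presentation class II genes in macrophage or monocyte-like cells had a median of 0.047 for hydrogel against untreated. Dissociation and stress genes in macrophage or monocyte-like cells had a median of -0.26 for hydrogel against untreated. 333 genes were 2-fold higher in macrophage or monocyte-like cells for CO hydrogel against untreated.

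With no minimum count and 0.5 counts added, 1293 genes were 2-fold higher and 1483 genes were 2-fold lower in fibroblast-like cells for CO hydrogel against hydrogel. 2384 genes were 2-fold higher and 1604 genes were 2-fold lower in fibroblast-like cells for CO hydrogel against untreated. 2938 genes were 2-fold higher and 1431 genes were 2-fold lower in fibroblast-like cells for hydrogel against untreated. 2446 genes were 2-fold higher and 932 genes were 2-fold lower in macrophage or monocyte-like cells for CO hydrogel against hydrogel. 3206 genes were 2-fold higher and 1462 genes were 2-fold lower in macrophage or monocyte-like cells for CO hydrogel against untreated. 2015 genes were 2-fold higher and 1464 genes were 2-fold lower in macrophage or monocyte-like cells for hydrogel against untreated.

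Without genes over 5 times higher in another class, an alternative chosen after seeing the data, inflammatory cytokines and chemokines genes in fibroblast-like cells had a median of -0.040 for CO hydrogel against hydrogel. Growth factors genes in macrophage or monocyte-like cells had a median of -1.19 for CO hydrogel against hydrogel. Complement and stromal chemokines genes in macrophage or monocyte-like cells had a median of -0.73 for CO hydrogel against hydrogel and -0.11 for CO hydrogel against untreated.

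With cells thinned to 2000 UMIs, the share of fibroblast-like cells with a Cxcl14 UMI was 16.6% untreated, 16.7% hydrogel and 13.2% CO hydrogel. Cxcl14-positive fibroblast-like cells were 2.68% untreated, 2.86% hydrogel and 5.78% CO hydrogel of all cells. The mean log2 ratio of Hacd1 with Cxcl14 was 0.046.

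With no thinning, the share of fibroblast-like cells with a Cxcl14 UMI was 31.2% untreated, 29.1% hydrogel and 23.9% CO hydrogel. Cxcl14-positive fibroblast-like cells were 3.80% untreated, 4.18% hydrogel and 9.38% CO hydrogel of all cells. 1249 genes were higher with Cxcl14 in all 3 libraries. 2298 genes were lower with Cxcl14 in all 3 libraries. The median with Cxcl14 of fibroblast progenitor genes, untreated library was -0.11. The median with Cxcl14 of fibrillar collagen and wound matrix genes, CO hydrogel library was -0.22.

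With Cxcl14-negative cells weighted to the clusters of the positive cells, an alternative chosen after seeing the data, the mean log2 ratio of Prdm1 with Cxcl14 was 0.36. The mean log2 ratio of Tpm2 with Cxcl14 was 0.27.

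Depth limits the class with the fewest UMIs per cell most. Neutrophil-like cells of the CO hydrogel library had 595533 UMIs in 445 cells, against 46583473 UMIs in 4960 fibroblast-like cells, and 2857 genes reached the count minimum in the former for CO hydrogel against hydrogel, against 10641 in the latter.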

Other observations

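The values in this part were chosen only after they were seen, and no explanation was tested for them.

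Interferon response genes were read in 3 further classes. In endothelial-like cells their median log2 ratio was 2.63 for CO hydrogel against untreated, 2.21 for hydrogel against untreated and 0.12 for CO hydrogel against hydrogel. In mural-like cells it was 1.02, 1.05 and 0.31 in the same order, but 9 of 12 members for hydrogel against untreated were over 5 times higher in another class, and the other 3 had a median of -0.04. In neutrophil-like cells it was 0.79, 0.77 and 0.07, and all 3 turned negative with TMM factors (-0.37, -0.17 and -0.15), which moved all ratios to the untreated library in that class by 1.16 for the CO hydrogel and 0.94 for the hydrogel. This class leaves out cluster 13, led by the interferon-induced Rsad2 and Isg15 and scoring highest for neutrophils, with 107 untreated, 913 hydrogel and 11 CO hydrogel cells. With it counted as neutrophil-like the medians were 0.88, 1.74 and -0.80, and with no doublets removed 0.90, 1.84 and -0.82, so the value for CO hydrogel against hydrogel turned. Inflammatory genes in neutrophil-like cells had medians of -1.46, -1.10 and -0.68, and -2.62, -2.04 and -0.90 with TMM factors.

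Keratinocyte-like cells, of which the untreated library held 93, had the highest Cxcl14 level of the classes read, 515.7 CPM untreated, 550.2 with the hydrogel and 1151 with the CO hydrogel.

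Hox genes differ with body position, and several differed between the fibroblast-like cells of the libraries. In the untreated, hydrogel and CO hydrogel libraries Hoxc10 was at 7.94, 0.644 and 0.0644 CPM, Hoxc8 at 34.9, 77.1 and 40.7, Hoxc9 at 17.7, 24.0 and 19.1, Hoxb7 at 5.80, 1.80 and 4.25 and Hoxc4 at 4.43, 8.32 and 13.1, while Hoxd9 was at 3.42, 2.75 and 2.86. The labels do not give the body position of the wounds, so a difference in position between the specimens stays open for all ratios of fibroblast-like cells.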
